A study of Drosophila melanogaster with 36 samples.

How the data were processed

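Kc167 cells were electroporated with barcoded reporter libraries, 1 promoter per library, per the labels' protocols. The transposase was induced by heat shock at 37 °C, transfected cells were selected on day 3, and pools of 10000, 20000 or 50000 cells were grown for 2 weeks. Barcodes were read in genomic DNA, to correct for the abundance of each barcode, and in RNA, and inverse PCR linked each barcode to its insertion site. The 36 libraries belong to 10 pools (5 promoters with 2 biological replicates each); technical libraries of a pool were counted once. The labels number the promoters and do not describe them further, and no property of a promoter is assumed here.

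The authors deposited 1 table with a row per reporter, which gives its barcode, site, promoter, replicate, expression and the value of 112 chromatin tracks. The deposited expression values are on a log2 scale. The base is not given in the sources used here and was read from the values. In promoter 3 replicate 2, a pool with many repeated values, the 4 most frequent values from the commonest one upward were 0.97, 1.40, 1.73 and 2.00. Taken as the logarithm of a read number plus a constant, they give 2.86, 3.85 and 4.85 in base 2, which rise by 0.999 and 1.00, close to the step of 1 between whole reads. They rise by 0.688 and 0.691 in the natural base and by 0.284 and 0.291 in base 10. The same check on promoter 4 replicate 2 found no such series and settles nothing, so the base rests on 1 pool. The mean of each pool lay between -0.035 and 0.12, and a scaling within pools is not stated in the sources used here. The track values are a score of unknown scale, as deposited by the authors, and they were used only by rank. Their origin is not given in the sources used here. Sites were mapped to build dm3 per the submitters' processing notes. The aligner, the grouping of barcodes and the filters are not given in the sources used here. Mapping errors, errors in barcode reads and low read numbers, which were not part of the table, would each add noise to single reporters. Such noise lowers correlations, but errors that enter 1 reporter more than once, within a pool or between pools, would raise them. The size of either effect is unknown. Identical values shared by 5 or more reporters of a pool, as low read numbers give, made up 24.5% of promoter 0 replicate 1, 16.6% of promoter 4 replicate 2, 15.9% of promoter 3 replicate 2 and 14.6% of promoter 2 replicate 1, and at most 7.28% in the other pools.

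Of 75195 rows, 76 repeated a barcode, site and pool and were removed, leaving 75119 reporters. The pool median was subtracted. For windows of 200 kb, the mean was taken over reporters, with at least 5 per window and pool. Window means were correlated between pools and set against 1000 circular shifts. Windows with a value in at least 8 of 10 pools were tested with limma 3.58.1 in R 4.3.3 (one-sample test of the mean, F test between promoters, and each promoter against the other pools), with the number of reporters as weights and Benjamini-Hochberg adjustment at 0.05. Neighbouring insertions were the next ones along a chromosome in the same pool. Differences between chromosomes, proximal parts, strands and the correlations with tracks were computed per pool, and their means were tested by an exact two-sided sign-flip permutation test over the pools (1024 sign patterns for 10 pools). Differences between promoters were tested by the share of variance between promoters over all 945 regroupings of the pools. The proximal part of an arm is the 2 Mb next to its centromeric end as covered by the insertions. The table has no separate heterochromatin scaffolds, so that planned contrast used this proximal part. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

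The named windows are the 10 highest and 10 lowest among those past the threshold with the same sign in each pool, a rule set before the data were examined. Only 2 windows met it with the pool median removed. The others named come from a list that follows the same rule with the pool mean removed, and the 2 highest and 2 lowest of that list are printed with the range of the rest. A first such list used promoters 1 to 4; it was exchanged after the simulation below showed false low windows with the pool median removed. Both lists were drawn up after the data were seen. The named tracks follow the same rule with 12 on each side, carried over to tracks after the data were seen. Comparisons that need gene positions (inside and outside genes, orientation to a host gene, distance to gene starts, gene groups) were planned and not made, because no annotation of build dm3 was among the sources used here. The table has no column of chromatin classes.

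The procedure was tested on simulated data, the deposited values shuffled between reporters of a pool. Without any effect, limma called 0 of 261 windows, 1 of 204 windows in the test between promoters, and 0 of 112 tracks were called. The shuffle also removed the likeness of neighbouring reporters and the regional pattern that the pools share. It therefore cannot show how often a track or an arm is called through regional clustering alone. With 20 windows raised and 20 lowered by 2 log2 units in each pool, 20 and 20 were recovered, and 7 further windows were called, 7 of them as low. With the pool mean removed, 20 and 20 were recovered and 0 further windows were called. The simulated shift was equal in each pool and larger than the means of the 2 windows called in the data (0.83 and 0.89). Its full recovery therefore does not give the power in the data. A simulated difference of 0.5 on the X was recovered as 0.5. This checks the arithmetic only, since a constant added to each X reporter must shift the difference of medians by that constant. A random effect per window gave a correlation of neighbours at 0 to 1 kb of 0.167, against 0.208 from its variance. Where expression was made to follow the H3K36ME3 track, that track ranked 1 of 112.

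The alternatives tried were means in place of medians and the reverse, promoters 1 to 4 alone, each pool left out in turn, the replicate number as a block, windows of 100 and 500 kb, minimums of 3 and 10 reporters, no weights, and proximal parts of 1 and 5 Mb. Added after the data were seen were the pool mean removed, division by the SD of the pool, removal of barcodes shared between pools, removal of tied values, neighbours at least 1 base apart, and tracks without chromosome 4 and the proximal 2 Mb. A reporter's expression was also predicted from the tracks by ridge regression (penalty 100), with each arm predicted from the other arms. The predictors were the ranks of the tracks at the site and, where stated, their mean over all insertions within 10 kb.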

Results

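Expression of reporter genes inserted at many places of the Drosophila genome was measured in Kc167 cells, a cultured line of Drosophila melanogaster. Each reporter carried one of 5 promoters, named promoter 0 to promoter 4 in the labels, and a random barcode that identifies it in DNA and in RNA. The reporters were integrated with the Sleeping Beauty transposase. Inverse PCR located each barcode, and the barcode reads in RNA were set against those in DNA to give its expression. The 36 libraries comprise 14 of barcode DNA, 12 of barcode RNA and 10 of integration sites. They fall into 10 pools of cells, 2 biological replicates for each of the 5 promoters, and the pool is the replicate in each test below. Tests of a mean over the 10 pools count the 2 pools of a promoter as independent. These 2 pools resembled each other. The share of variance between promoters was 0.944 for the X contrast and 0.842 for the chromosome 4 contrast. The p-values over 10 pools thus overstate the evidence that a result holds over promoters in general. The deposited table gave 75119 distinct reporters after 76 repeated entries were removed. The number of reporters ranged from 1164 in promoter 4 replicate 1 to 23183 in promoter 0 replicate 1. Promoter 0 had 26559 reporters over both pools, promoter 1 had 10235, promoter 2 had 26067, promoter 3 had 8445 and promoter 4 had 3813. Read numbers per barcode were not part of the table, so the depth behind a single value is unknown.

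The title of the series concerns how the genomic surroundings of housekeeping promoters relate to their expression, and the first comparison is the distribution of expression for each promoter. Promoter 3 had the widest distribution, with an SD of reporter expression of 3.03 ± 0.15 on the log2 scale (mean ± SD, n = 2 pools). The SD was lowest for promoter 0, at 1.67 ± 0.23, which is within the spread of promoter 4. By quartiles promoter 4 was the narrowest, at -0.27 to 1.07 and -0.14 to 0.81 in its pools. Those of promoter 0 were -1.31 to 1.265 and -1.02 to 0.79. The values for promoters 1, 2 and 4 were 2.44 ± 0.03, 1.86 ± 0.51 and 1.70 ± 0.27. Promoter 3 was broad above and below its median. Its quartiles were -2.21 to 2.70 and -2.08 to 2.49 in its pools, around medians of 1.15 and 0.97. Those of promoter 1 were -0.61 to 1.67 and -0.76 to 1.69. The share of weakly expressed reporters grows with this width and does not by itself show a separate tail. It was largest for promoter 3. In its 2 pools 27.3% (95% Wilson interval 25.8 to 28.9%) and 25.3% (24.2 to 26.5%) of reporters lay 8-fold or more below the pool median. The corresponding shares were 16.3% and 16.0% for promoter 1, 8.42% and 6.68% for promoter 4, and 3.82% and 0.918% for promoter 0. The pools of promoter 2 differed from each other, at 4.22% and 14.3%. These intervals cover counting error only.

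The pool medians were 1.06 ± 0.13 for promoter 3, 0.92 ± 0.06 for promoter 1, 0.53 ± 0.06 for promoter 4, 0.29 ± 0.16 for promoter 2 and -0.086 ± 0.017 for promoter 0 (log2, mean ± SD, n = 2 pools each). The pool medians differed between promoters (between-promoter share of variance 0.973, exact permutation test over 945 regroupings of the pools, p = 0.00106, the smallest it can give). The pool means lay between -0.035 and 0.12 (share of variance 0.852, exact permutation p = 0.0423). Whether the values were scaled within each pool is not stated in the sources used here, so the levels are not read as promoter strength. The mean lay below the median by 0.97 ± 0.10 for promoter 3 and 0.82 ± 0.03 for promoter 1 (mean ± SD of the 2 pools) and above it by 0.066 ± 0.004 for promoter 0. For the SD of the pools the share of variance was 0.870 (exact permutation p = 0.0286), which missed 0.05 after adjustment over 9 quantities (adjusted p = 0.0599). The unadjusted p also rose above 0.05 when promoter 0 replicate 2, either pool of promoter 1 or either pool of promoter 3 was left out, with p from 0.0519 to 0.116. Pairs of promoters have 2 pools each, for which the smallest exact p is 0.333, so no pair was tested on its own.

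**Figure D1:**
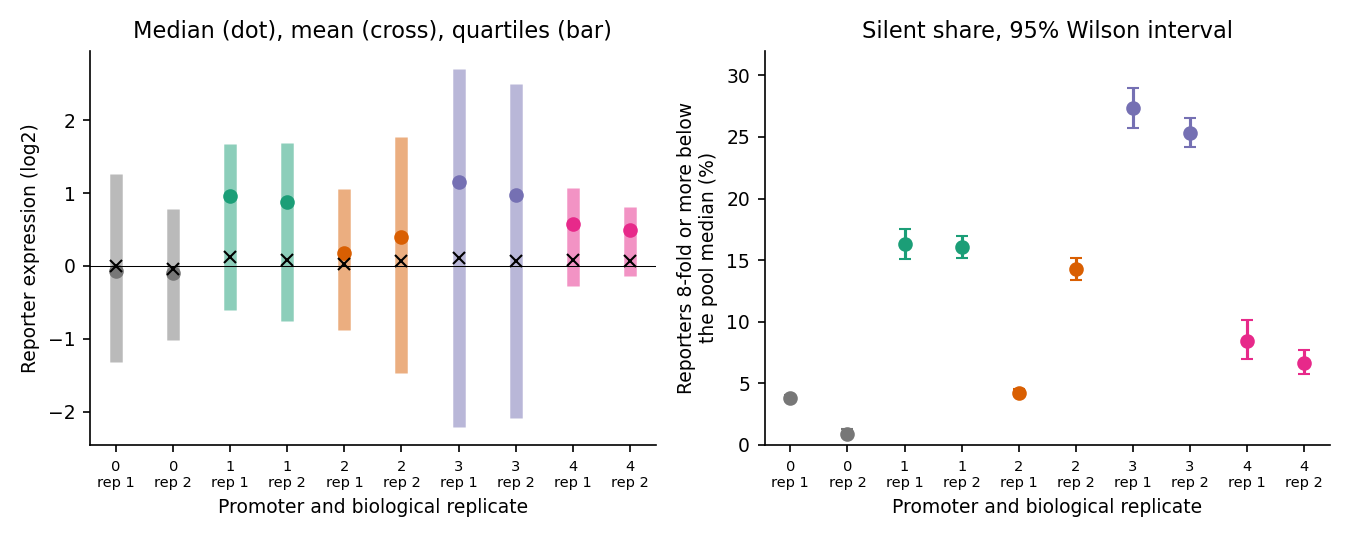
Left, reporter expression (log2, as deposited) in each of the 10 pools, with the median as a dot, the mean as a cross and the quartiles as a bar. Right, the percentage of reporters 8-fold or more below the pool median with its 95% Wilson interval; the pools of promoter 3 stand at 27.3% and 25.3% and those of promoter 0 at 3.82% and 0.918%.

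Whether expression followed the place of insertion was asked by averaging reporters over windows of 200 kb, with at least 5 reporters in each pool, and correlating the windows between pools. The same windows were high or low with promoters 1 to 4. Between pools of different promoters among these 4, the mean Pearson r across windows was 0.578 (24 pairs of pools, 0.335 to 0.722, mean Spearman rho 0.505). Between the 2 replicates of a promoter it was 0.774 for promoter 1, 0.714 for promoter 2, 0.776 for promoter 3, 0.203 for promoter 0 and 0.0932 for promoter 4, with a mean of 0.512 (mean Spearman rho 0.496). Promoter 4 shared only 31 windows between its replicates. Promoter 0 correlated with promoters 1 to 4 at a mean r of 0.198 (16 pairs, -0.218 to 0.291, mean Spearman rho 0.183). Each of these 3 means exceeded all 1000 circular shifts of the windows along the genome (one-sided permutation p = 0.001, the smallest they can give), which averaged -0.0020, 0.00064 and 0.00060. These correlations are across windows, which are not independent replicates.

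Reporters that lay close together were expressed at similar levels, and the similarity fell with distance. The mean Pearson r of neighbouring insertions in a pool was 0.353 ± 0.178 (SD, n = 10 pools) at 0 to 1 kb, 0.354 ± 0.209 at 1 to 5 kb, 0.305 ± 0.160 at 5 to 20 kb and 0.202 ± 0.112 at 20 to 100 kb. In these 4 classes r was above 0 in 10 of 10 pools (exact two-sided sign-flip permutation test over pools, p = 0.00195 in each, the smallest 10 pools can give). At 100 to 500 kb it was 0.0911 ± 0.0862 over the 8 pools with enough pairs (6 of 8 above 0, exact permutation p = 0.0312). Over the 8 pools with a value in both classes, the nearest class exceeded the farthest by 0.308 (exact permutation p = 0.00781). Promoter 3 had the most similar neighbours, at 0.615 ± 0.031 for 0 to 1 kb (n = 2 pools), against 0.388 ± 0.072 for promoter 1, 0.359 ± 0.127 for promoter 2, 0.220 ± 0.052 for promoter 4 and 0.183 ± 0.165 for promoter 0. The call at 100 to 500 kb was lost when either pool of promoter 1, either pool of promoter 3, promoter 2 replicate 2 or promoter 4 replicate 2 was left out, with an exact p of 0.0625 each time and r between 0.0789 and 0.0891.

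**Figure D2:**
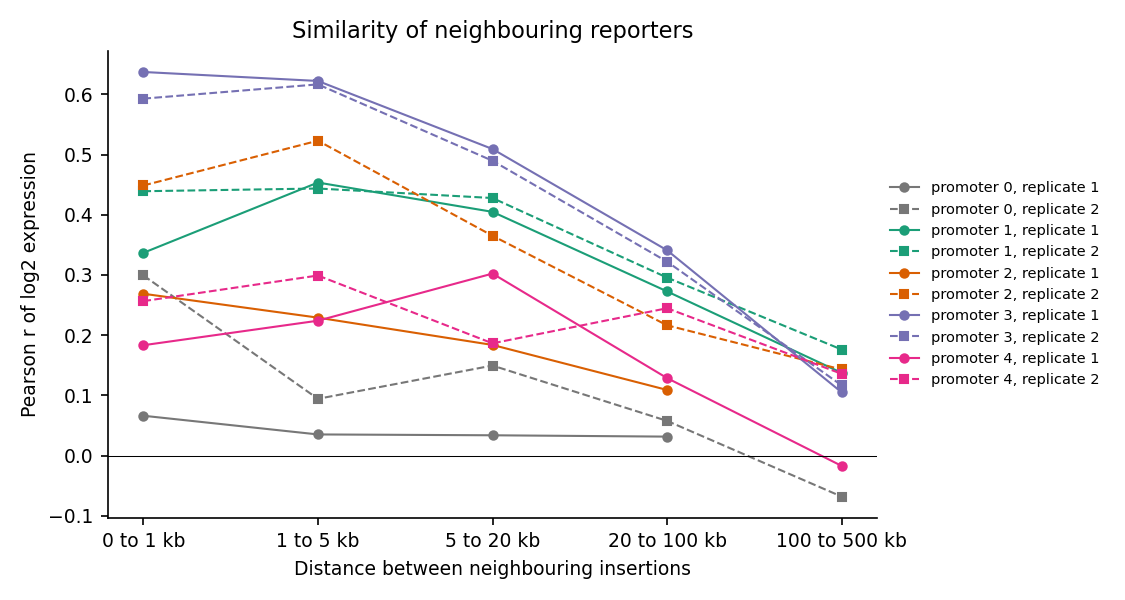
Pearson r of log2 expression between neighbouring insertions (vertical axis) against the distance class (horizontal axis), one line per pool, coloured by promoter. Both pools of promoter 3 start near 0.615 and fall to about 0.111 at 100 to 500 kb, and promoter 0 lies lowest from 1 kb on; promoter 0 replicate 1 and promoter 2 replicate 1 have too few pairs for the last class.

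Reporters on chromosome 4, a small chromosome rich in heterochromatin proteins, were expressed above those on the large autosome arms with each promoter. The difference of medians was 0.65 ± 0.28 on the log2 scale, a 1.57-fold difference (mean ± SD, 10 of 10 pools, exact two-sided sign-flip permutation p = 0.00195, adjusted p = 0.00391 over 4 contrasts). It was 1.05 ± 0.23 for promoter 3, 0.81 ± 0.10 for promoter 1, 0.57 ± 0.13 for promoter 2, 0.43 ± 0.09 for promoter 4 and 0.40 ± 0.17 for promoter 0 (n = 2 pools each). Chromosome 4 held 744 of the reporters.

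On the X chromosome, reporters were expressed below those on the large autosome arms, by -0.31 ± 0.47 (7 of 10 pools lower, exact permutation p = 0.0293, adjusted p = 0.0293), and most of this came from promoter 3. The difference was -1.16 ± 0.19 for promoter 3, -0.18 ± 0.06 for promoter 1, -0.18 ± 0.21 for promoter 2 and -0.083 ± 0.168 for promoter 4 (n = 2 pools each), and it was above 0 for promoter 0, at 0.053 ± 0.001. Without promoter 3 the mean was -0.099 over 8 pools (exact permutation p = 0.117). Leaving out single pools ended the call in 6 cases, with exact p between 0.0547 and 0.0586. The means were then -0.32 without promoter 1 replicate 1, -0.33 without promoter 1 replicate 2, -0.31 without promoter 2 replicate 2, -0.20 without promoter 3 replicate 1, -0.23 without promoter 3 replicate 2 and -0.32 without promoter 4 replicate 1.

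**Figure D3:**
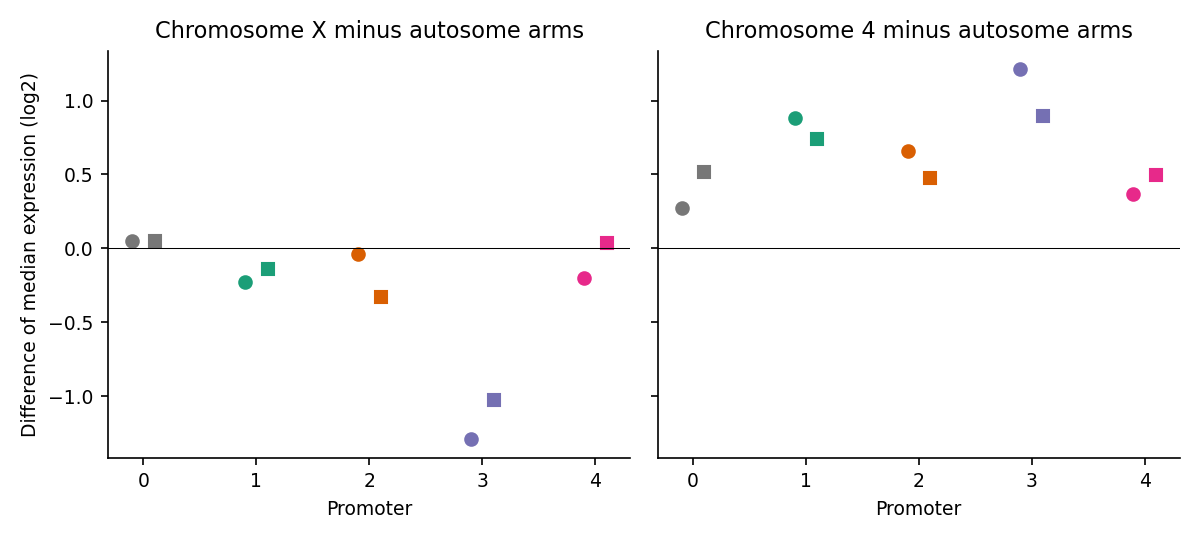
Difference of median reporter expression (log2) between chromosome X (left) or chromosome 4 (right) and the large autosome arms 2L, 2R, 3L and 3R, by promoter; circles are replicate 1 and squares replicate 2. Chromosome 4 lies above 0 in 10 of 10 pools, and the pools of promoter 3 lie lowest on the X, with a mean of -1.16.

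The autosome arms differed as well, in a comparison that was not planned. Each was set against the other large arms, the X included, and the X was low with promoter 3. Reporters on 2R were expressed above those on the other large arms by 0.28 ± 0.29 (10 of 10 pools, exact permutation p = 0.00195, adjusted p = 0.00391), and those on 2L below by -0.21 ± 0.20 (0 of 10 pools higher, same p). For 3L and 3R the differences were 0.032 ± 0.092 and 0.074 ± 0.123, with adjusted p of 0.316 and 0.136. With promoter 3 the differences reached 0.81 ± 0.19 for 2R and -0.53 ± 0.02 for 2L (n = 2 pools). With promoters 0, 1, 2 and 4 they were 0.087, 0.187, 0.178 and 0.120 for 2R. For 2L they were -0.062, -0.188, -0.159 and -0.099 with these promoters.

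The 2 Mb next to the centromere, where heterochromatin borders the arms, differed in opposite directions on different arms. Proximal reporters of the X were expressed below the rest of the X by -0.88 ± 1.06 (9 of 10 pools, exact permutation p = 0.00586, adjusted p = 0.0146 over 5 arms), with -2.72 ± 0.58 for promoter 3 and -1.06 ± 0.05 for promoter 1 (n = 2 pools). For promoters 0, 2 and 4 the differences were smaller, at -0.13 ± 0.26, -0.20 ± 0.06 and -0.32 ± 0.40 (n = 2 pools each). Proximal reporters of 2L were above the rest of 2L by 0.49 ± 0.68 (8 of 10 pools, adjusted p = 0.0195), with 1.25 ± 1.48 for promoter 3 (n = 2 pools), and the mean was 0.28 without promoter 3 replicate 1. Proximal reporters of 3R were above the rest of 3R by 0.32 ± 0.34 (9 of 10 pools, adjusted p = 0.0146). The differences for 2R and 3L were 0.13 ± 0.35 and -0.15 ± 0.47, both with an adjusted p of 0.352. Over the 5 arms together the difference was 0.053 ± 0.073 (9 of 10 pools, exact permutation p = 0.0293). It was lost without promoter 0 replicate 2, promoter 1 replicate 2, promoter 2 replicate 2 or either pool of promoter 4, with values of 0.034 to 0.055 and p of 0.0508 to 0.0625. It was also lost with 1 Mb in place of 2 Mb (0.035, exact permutation p = 0.342) and with means in place of medians (0.048, exact permutation p = 0.172).

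The strand of insertion was planned as a negative control, for which no difference was awaited. Reporters on the plus strand were expressed below those on the minus strand by -0.070 ± 0.064 in 10 of 10 pools (exact permutation p = 0.00195, adjusted p = 0.00391). It was -0.18 for promoter 3 and -0.041 over the 8 pools of the other promoters (exact permutation p = 0.00781). With means in place of medians the difference was -0.033 (exact permutation p = 0.135). With medians the control thus did not hold, at the p also given for chromosome 4 (0.65), 2R (0.28) and 2L (-0.21). These differences were larger in size, but the proximal contrast over the arms together (0.053) was smaller. Such a p shows a sign shared by the pools. It does not show that a chromosome, arm or track differs beyond what regional clustering alone would give.

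The deposited table gives, for each insertion site, the value of 112 chromatin protein and histone mark tracks. Reporters were weakest where lamin (LAM), the structural protein under the nuclear envelope, and SUUR, a protein that slows replication of silent chromatin, were high. The most positive tracks were DMAP1, the chromodomain protein MRG15 and CG7946, and the most positive of the histone marks was methylation of histone H3 at lysine 4 (H3K4ME2). The mean Spearman rho over pools was -0.285 ± 0.106 for SUUR, -0.255 ± 0.099 for LAM, 0.259 ± 0.088 for DMAP1, 0.250 ± 0.084 for MRG15, 0.245 ± 0.087 for CG7946 and 0.232 ± 0.088 for H3K4ME2 (SD, n = 10 pools). Each had the same sign in 10 of 10 pools (exact sign-flip permutation p = 0.00195, Benjamini-Hochberg adjusted p = 0.00277 over 112 tracks). With promoters 1 to 4, the 20% of sites with most lamin were expressed below the 20% with least by -1.93 ± 1.30 on the log2 scale (SD, n = 8 pools), and for SUUR the difference was -1.94 ± 1.22. For DMAP1 the top 20% exceeded the bottom 20% by 1.81 ± 1.19, for MRG15 by 1.66 ± 1.14, for CG7946 by 1.67 ± 1.22 and for H3K4ME2 by 1.45 ± 1.02. With promoter 0 the same differences were -0.44 for lamin, -0.59 for SUUR, 0.48 for DMAP1 and 0.64 for H3K4ME2, and with promoter 3 they were -3.77, -3.50, 3.44 and 2.57. These gaps are in log2 units and grow with the spread of a pool, which was largest for promoter 3. By rank, promoter 3 was not the strongest for each track. For SUUR rho was -0.365 with promoter 3, -0.367 with promoter 1 and -0.351 with promoter 2. For H3K4ME2 these values were 0.270, 0.287 and 0.320, for LAM -0.358, -0.325 and -0.275, and for DMAP1 0.338, 0.306 and 0.320.

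Of the 112 tracks, 78 correlated positively and 25 negatively with expression at an adjusted p under 0.05, and 9 did not pass. The 12 most positive tracks with the same sign in each pool also included the deacetylases SIR2 (0.228 ± 0.089) and RPD3 (0.195 ± 0.077), the Myc partner MAX (0.209 ± 0.071), H3K79ME2 (0.206 ± 0.078), the cohesin subunit RAD21 (0.188 ± 0.066), H3K36ME3 (0.186 ± 0.061), the RNA polymerase II subunit RPII18 (0.184 ± 0.069) and the boundary protein BEAF32 (0.183 ± 0.071). The 12 most negative also included CG7006 (-0.194 ± 0.051), D1 (-0.174 ± 0.054), the Polycomb mark H3K27ME3 (-0.171 ± 0.060), the insulator protein SU.HW. (-0.157 ± 0.053), SBP2 (-0.157 ± 0.047), CG3313 (-0.153 ± 0.055), linker histone H1 (-0.152 ± 0.049), EFF (-0.137 ± 0.048), CG15436 (-0.134 ± 0.046) and PCL (-0.125 ± 0.046). The pools fall into 2 sets that share barcodes (promoters 0 and 2, and promoters 1, 3 and 4); for LAM the mean rho was -0.193 and -0.296 in these, and for DMAP1 it was 0.223 and 0.283. The correlation was smallest in size with promoter 0 for 17 of the 24 tracks and with promoter 4 for the other 7. It differed between promoters for 41 of the 112 tracks (exact permutation of the pools between promoters, adjusted p under 0.05), 7 of them among the 24.

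**Figure D4:**
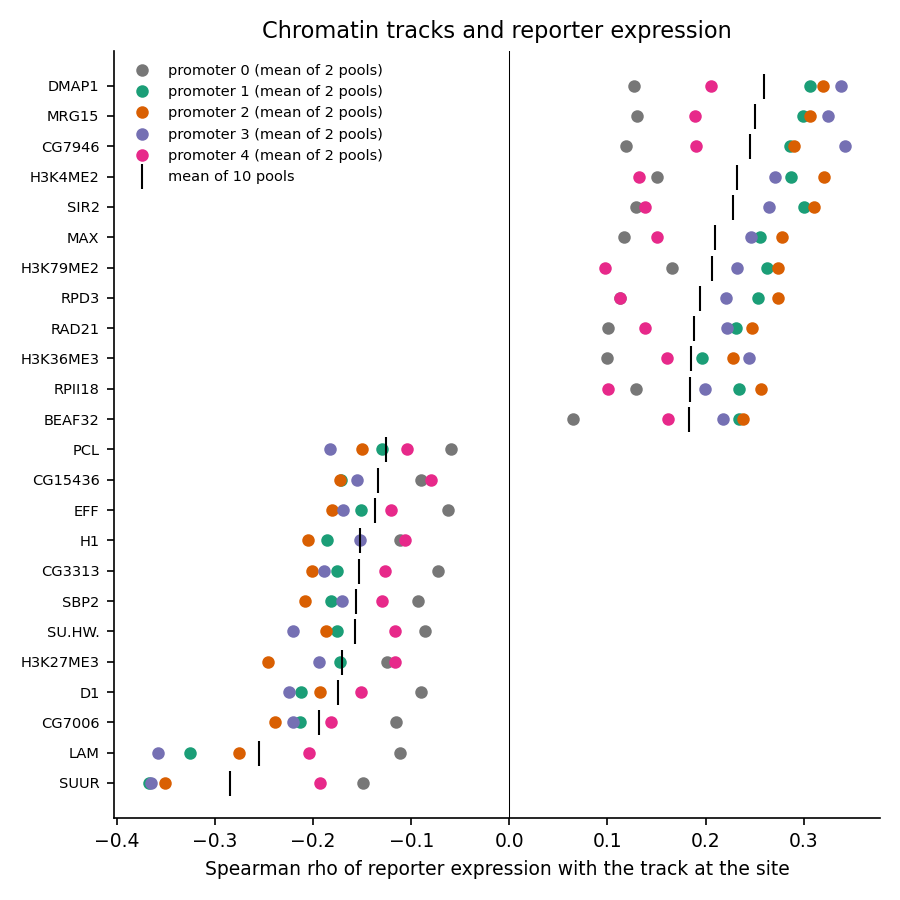
Spearman rho of reporter expression with the value of each track at the insertion site (horizontal axis) for the 12 most positive and 12 most negative tracks; dots are the mean of the 2 pools of a promoter and ticks the mean of the 10 pools. The rho of promoter 0 for LAM is -0.111 and that of promoter 3 is -0.358.

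Grouped by their known function, the tracks separated as follows, with groups drawn up after the values were seen. The 4 tracks of lamina and silent chromatin (LAM, SUUR, D1, H1) and the 7 tracks placed in the Polycomb group (H3K27ME3, PCL, PC, SCE, E.Z., PHO and RYBP) were negative, with group means of -0.217 ± 0.074 and -0.0968 ± 0.0328. H3K27ME3 was the lowest of the Polycomb group, and PC stood at -0.125 ± 0.038. Of tracks with a known Polycomb link that were not placed there, DSP1 (0.135 ± 0.052), PHOL (0.111 ± 0.033), CAF1 (0.0973 ± 0.0480) and LOLAL (0.0640 ± 0.0275) were positive in 10 of 10 pools, and GAF was not called. With these 5 added, the mean of the 12 tracks was -0.0237 ± 0.0160, so the size of the group mean depends on the members chosen. The 5 active marks and their readers (0.206 ± 0.070), the 6 tracks of the transcription machinery (0.127 ± 0.051), the 4 acetyltransferase complex tracks (0.139 ± 0.052) and the 4 remodellers and histone chaperones (0.121 ± 0.051) were all positive. Of the 5 deacetylases and corepressors 4 were positive, and GRO, the corepressor Groucho, was negative at -0.107 ± 0.040. The insulator proteins were divided, with BEAF32, DWG (0.118 ± 0.041) and CTCF (0.0253 ± 0.0226) positive, SU.HW. negative and GAF not called (-0.0138 ± 0.0280, adjusted p = 0.162). The counts rest on the tests of the single tracks (adjusted p under 0.05 over 112 tracks), and the group means are given as values without a test, since the members were chosen after their values were seen.

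Windows of 200 kb whose reporters were high or low over the pools were sought with limma, weighted by the number of reporters. Promoter 0 replicate 1 (23183 reporters) and promoter 2 replicate 1 (20488) had by far the most reporters. The window means therefore lean on these pools and do not weigh all promoters alike. Of 261 windows tested, 2 were high and 0 were low at an adjusted p under 0.05, and 44 high and 58 low windows had an unadjusted p under 0.05. Coordinates are those of the deposited table, build dm3 per the submitters' processing notes, and genes in the windows are not analysed here. The first window spans 19400001 to 19600000 on X, with a mean of 0.83 ± 0.16 (SE) above the pool medians in 10 of 10 pools and 179 reporters (limma, adjusted p = 0.0318). The second spans 11000001 to 11200000 on 3R, with 0.89 ± 0.17 in 8 of 8 pools and 134 reporters (limma, adjusted p = 0.0318). Both lay in chromatin of low SUUR (median percentiles of the sites 20.3 and 16.7) and high DMAP1 (86.6 and 85.3). Without weights, with promoters 1 to 4 and with the replicate number as a block, both counts were higher and low windows outnumbered high ones, as given below. Leaving out 1 pool gave 1 to 15 high and 0 to 13 low windows. The counts were 11 and 13 without promoter 0 replicate 1, 11 and 3 without promoter 0 replicate 2, and 15 and 7 without promoter 3 replicate 1. The high count was 1 without either pool of promoter 1, promoter 2 replicate 2, promoter 3 replicate 2 or promoter 4 replicate 2.

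The mean over all windows and pools was -0.15 with the pool median removed and 0.14 with the pool mean removed, so counts of high and low windows are relative to these shifts. With the pool mean removed, an alternative chosen after the data were seen, limma called 48 high and 18 low windows (84 and 32 at an unadjusted p under 0.05), and both windows above were among the high ones. Of these, 30 high and 10 low windows had the same sign in each pool. High windows were 3 of 3 on chromosome 4, 14 of 45 on 2R, 12 of 61 on 3R, 9 of 59 on X, 7 of 50 on 3L and 3 of 43 on 2L. The low windows were 7 on 2L, 5 on X, 4 on 3L and 2 on 3R. The high windows had median percentiles of 35.5 for LAM and 66.4 for H3K4ME2, against 67.4 and 36.1 in the low windows. The lowest of those with the same sign in each pool spanned 16400001 to 16600000 on 2L (-1.90 ± 0.41 SE, 8 of 8 pools below 0, adjusted p = 0.00938, 127 reporters), where the median percentiles were 83.9 for PC, 71.5 for H3K27ME3, 69.2 for SUUR and 45.7 for LAM. The promoters differed in size there (limma F test, adjusted p = 0.0170), with promoter 3 at -2.56 relative to the others (limma, adjusted p = 0.0318). Next came 22000001 to 22200000 on X (-1.83 ± 0.37 SE, 9 of 9 pools below 0, adjusted p = 0.00691), where the median percentiles were 35.0 for PC, 45.7 for H3K27ME3, 86.5 for SUUR and 87.6 for LAM. The promoters differed in size here as well (limma F test, adjusted p = 0.00867). Relative to the other pools, promoter 0 stood at 2.18 (limma, adjusted p = 0.0315) and promoter 3 at -2.82 (limma, adjusted p = 0.0209). With the pool median removed, these 2 lowest windows had means of -2.28 and -2.15 and just missed the threshold (limma, adjusted p = 0.0511 each). The highest with the pool mean removed were the 2 high windows also called with the pool median removed (1.17 ± 0.22 SE on X and 1.15 ± 0.20 SE on 3R). Over the 10 highest and 10 lowest windows named by the rule, LAM ranged from 45.7 to 87.6 in the low ones. In the high ones it started at 13.7, and 1 of the 10, from 9600001 to 9800000 on 3L, lay inside the range of the low ones.

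Whether the effect of a window depended on the promoter was tested with limma on the same windows. The weights were the same, so the pools that promoter 3 was set against leaned on the same large pools. The promoters differed in 26 of 204 windows at an adjusted p under 0.05. With the pool median removed, promoter 3 differed from the other promoters in 8 of 261 windows and was lower in 8 of these, by -3.65 at 20800001 to 21000000 on X (adjusted p = 0.0030), -3.57 at 6800001 to 7000000 on 3R (adjusted p = 0.0349) and -3.26 at 11200001 to 11400000 on 3L (adjusted p = 0.0130). Promoters 0, 1, 2 and 4 had 0 such windows in limma, and 59, 20, 3 and 1 at an unadjusted p under 0.05. Divided by the SD of the pool, a scaling chosen after the data were seen, promoter 3 had 0 windows in limma (32 at an unadjusted p under 0.05) and promoter 0 had 36. The same scaling took the count of 26 to 15. Removal of the pool mean took the count of promoter 3 from 8 to 53, with promoter 3 higher in 34 and lower in 19, so the one-sided direction depended on the centring. Of the 8 windows, 5 were still called lower there. Windows with promoter 3 higher were also called with medians per window (17 of 50), without weights (10 of 37), with windows of 100 kb (2 of 3) and 500 kb (2 of 8), and without promoter 2 replicate 2 (9 of 17). The replicate number as a block took the count to 3. With promoters 1 to 4 alone the promoters differed in 0 windows in limma (29 at an unadjusted p under 0.05). Only 3 of the 8 windows of promoter 3 had enough pools to be tested in that setting. The drop in counts is therefore in part a loss of windows. Over the settings tried, the count of 26 ranged from 0 to 111 and that of 8 from 0 to 53.

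The count of 26 windows also depended on single pools. It was 0 in limma without promoter 0 replicate 1 (14 at an unadjusted p under 0.05). It was 11 and 3 without replicates 1 and 2 of promoter 1, 17 without either pool of promoter 2, 14 and 11 without replicates 1 and 2 of promoter 3, and 15 and 3 without those of promoter 4. The count of 8 windows for promoter 3 became 1 and 2 without replicates 1 and 2 of promoter 0, 1 and 5 without those of promoter 1, 1 and 17 without those of promoter 2, and 3 and 2 without those of promoter 3. In the leave-outs fewer windows had values in 8 pools, and 2 to 8 of these 8 windows were tested. For promoter 0 the count became 19 without promoter 2 replicate 1. For promoter 1 it became 1 without promoter 1 replicate 2 and 2 without promoter 3 replicate 1.

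Insertions were spread over the whole genome covered by the table. The density was 584 reporters per Mb on 2L, 631 on 2R, 638 on 3L, 661 on 3R, 655 on X and 615 on chromosome 4, over the span from the first to the last insertion. The counts departed from proportionality to these spans (chi-square 136, 5 degrees of freedom), and the X carried 1.06 ± 0.07 times the density of the autosome arms (mean ± SD, n = 10 pools, exact permutation p = 0.0332).

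The labels give no sequencing batch, but the table itself divides the pools. A barcode at the same site occurred in more than 1 pool for 3679 reporters, and the pools that shared them formed 2 sets, promoters 0 and 2, and promoters 1, 3 and 4. Within the first set the smallest exact p is 0.125 and within the second it is 0.0312. Chromosome 4 exceeded the autosome arms by 0.48 ± 0.16 in the first set (4 of 4 pools, exact permutation p = 0.125) and by 0.77 ± 0.30 in the second (6 of 6 pools, exact permutation p = 0.0312). The X lay at -0.065 ± 0.181 in the first (exact permutation p = 0.875) and -0.47 ± 0.54 in the second (5 of 6 pools lower, exact permutation p = 0.0625), and the 4 pools of the first set could not have passed 0.05. The proximal 2 Mb of the arms together lay at 0.087 ± 0.097 (exact permutation p = 0.125) and 0.030 ± 0.050 (exact permutation p = 0.219), and the strand difference at -0.049 ± 0.029 (exact permutation p = 0.125) and -0.083 ± 0.079 (exact permutation p = 0.0312). The r of neighbours at 0 to 1 kb was 0.271 ± 0.157 in the first set and 0.408 ± 0.182 in the second, and that at 20 to 100 kb was 0.104 ± 0.082 and 0.268 ± 0.076. In the window correlations promoter 2 was as close to promoters 1, 3 and 4, of the other set (mean r 0.589, 12 pairs), as these were to each other (0.567, 12 pairs), while promoter 0 correlated with promoter 2, of its own set, at 0.267 (4 pairs) and with the other set at 0.175 (12 pairs). Each promoter lies in 1 set, so a difference between promoters of different sets cannot be separated from a difference between the sets.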

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

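The tests of shared barcodes, of the spread of promoter 3, of the regions of the X, of noise and of tied values were chosen after the result was seen; that of the tracks at the X sites was set before. Several quantities had an unadjusted p under 0.05 for a difference between promoters, by an exact permutation of the pools over 945 regroupings. The share of variance between promoters was 0.944 for the X contrast (exact permutation p = 0.0466), 0.842 for the chromosome 4 contrast (p = 0.0201) and 0.870 for the SD of expression (p = 0.0286). For the correlation of neighbours it was 0.817 at 0 to 1 kb (p = 0.0466), 0.878 at 1 to 5 kb (p = 0.0212), 0.869 at 5 to 20 kb (p = 0.0275) and 0.883 at 20 to 100 kb (p = 0.0339). After Benjamini-Hochberg adjustment over the 9 quantities tested, each of these 7 had an adjusted exact permutation p of 0.0599 and missed 0.05. They are listed by their unadjusted p, a rule that replaced the adjusted p after the values were seen. The promoters differed in 26 windows in limma and promoter 3 from the others in 8, and the correlation with expression differed between promoters for 41 of the 112 tracks.

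The table held 2441 matches of a barcode at the same site in 2 pools, a signal in columns that the comparisons did not use. Same-site pairs with different barcodes numbered 2736, which with 72999 distinct barcodes gives 0.0375 matches by chance, so the count of 2441 argues against chance reuse. Only 46.8% of the matches joined the 2 pools of one promoter, which argues against cells common to these pools as the whole source. Of the 1298 matches between different promoters, 1.85% fell outside the sets of promoters 0 and 2 and of promoters 1, 3 and 4, as reads assigned to the wrong library among pools handled together would give. The sets were drawn from the matches themselves, so this share cannot decide, and that explanation may hold but stays open. The values of shared barcodes correlated at 0.151 to 0.659 between pools with at least 25 matches, except for promoter 0 replicate 1 and promoter 2 replicate 1, where r was -0.618 over 222 matches.

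The lower expression of promoter 3 on the X was weighed against 3 explanations. Divided by the pool SD, the difference was -0.38 in promoter 3 and no lower than -0.15 in another pool, which argues against its larger spread as the whole cause. After removal of the level predicted from the tracks, it was -0.65, from -1.16 before, and the lowest other pool was at -0.24. The tracks at the sites could thus account for part of it. An incomplete prediction would leave a difference even if the tracked chromatin caused all of it. This test therefore cannot say whether the tracks account for the rest. Without the 3 lowest of 12 windows of 2 Mb the difference was -0.88, against -0.24 in the lowest other pool, and 10 of the 12 windows lay below the pool median. A property of promoter 3 stays open as a hypothesis, as does any technical difference particular to its pools, since the test between promoters missed 0.05 after adjustment.

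The weak position effect of promoter 0 has 2 technical explanations that remain open, noise and low read numbers. A first test of noise took barcodes shared by the 2 pools of a promoter, whose values correlated at 0.288 for promoter 0 and at 0.422, 0.584, 0.428 and 0.484 for promoters 1 to 4, as noisier values would give. It was replaced after this result was seen, because shared barcodes may be misassigned reads. Corrected for the replicate correlations without shared barcodes, the r of promoter 0 with promoters 1 to 4 was 0.594 (95% bootstrap interval over windows 0.392 to 1.33), against 0.952 (0.693 to 1.13) among promoters 1 to 4. These intervals overlap, so noise and a different response to position cannot be told apart by it. Without tied values the r of its neighbours at 0 to 1 kb was 0.241 ± 0.113 (SD, n = 2 pools), against 0.242 for promoter 4, the lowest of the others. The gap is within the spread, so low read numbers may contribute and are not excluded. This test covered the nearest class only. With tied values kept, promoter 0 stood at 0.065 against 0.262 for promoter 4 at 1 to 5 kb. At 5 to 20 kb it stood at 0.092 against 0.244.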

How the results depend on the processing

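Planned were the exchange of means and medians, promoters 1 to 4, leave-outs, the replicate block, window sizes, minimums, weights and proximal parts; the settings that remove the pool mean, divide by the pool SD, drop shared barcodes or tied values, part neighbours or widen the Polycomb group were chosen after the data were seen. A result of one sign in 10 of 10 pools keeps it in each subset of them, so the leave-outs, the block and promoters 1 to 4 do not test the sign of the 24 named tracks, neighbours up to 100 kb, chromosome 4, 2L, 2R or strand. With other reporters or sites the named tracks kept direction and threshold in 72 of 72 cases. The contrasts of 2L, 2R and the proximal parts of 2L, 3R and X did so in 15 of 15 cases with means or fewer reporters, and these proximal parts in 33 of 33 cases with fewer pools. Among the main results 334 repeats kept direction and threshold, 29 lost the threshold and 74 counts moved by over 1.5 times. The 334 include repeats whose sign was fixed as described above. Of the results with a sign, 0 were seen to reverse. Counts of windows carry no sign, so a change of direction within them could not register here. Such a change occurred for promoter 3, with 34 windows higher and 19 lower when the pool mean was removed. Leaving out single pools gave 0.812 to 0.954 for the share of variance of the SD, 0.0789 to 0.114 for neighbours at 100 to 500 kb, 0.034 to 0.063 for the proximal contrast and -0.35 to -0.20 for the X; these have fewer pools, and the cause was not tested further. Without shared barcodes the r at 100 to 500 kb was 0.0837 (exact permutation p = 0.0547) and without tied values 0.0822 (p = 0.0703). The proximal contrast was 0.048 with means, 0.054 with promoters 1 to 4 and 0.035 with 1 Mb, and the strand difference was -0.033 with means; the cause was not tested.

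The window counts depended most on the processing. High windows, 2 with the planned setting, numbered 7 with medians per window, 15 with promoters 1 to 4, 4 and 0 with windows of 100 and 500 kb, 1 with at least 10 reporters, 23 without weights, 48 with the pool mean removed, 35 divided by the pool SD, 11 without shared barcodes, 32 without tied values and 1 to 15 in the leave-outs. Low windows, 0 with the planned setting, numbered 18 with promoters 1 to 4, 1 with windows of 100 kb, 57 without weights, 18 with the pool mean removed, 37 divided by the pool SD, 4 without shared barcodes, 17 without tied values and 0 to 13 in the leave-outs. Windows that differed between promoters, 26 as planned, numbered 16 with medians per window, 0 with promoters 1 to 4, 1 and 95 with windows of 100 and 500 kb, 111 with at least 3 reporters, 8 without weights, 15 divided by the pool SD, 10 without shared barcodes, 11 without tied values and 0 to 25 in the leave-outs; with at least 10 reporters this test gave no value. For promoter 3, with 8 as planned, they numbered 50 with medians per window, 1 with promoters 1 to 4, 3 with windows of 100 kb, 22 and 1 with at least 3 and 10 reporters, 37 without weights, 53 with the pool mean removed, 0 divided by the pool SD, 5 without shared barcodes, 16 without tied values and 1 to 17 in the leave-outs. For promoter 0, with 0 as planned, they were 1 with at least 3 reporters, 3 with the pool mean removed, 36 divided by the pool SD and 0 to 19 in the leave-outs; promoter 1 had 0 to 2 in the leave-outs and promoter 2 had 2 with promoters 1 to 4. The cause was not tested; in the simulation removal of the pool median added low windows, whereas in the data low windows rose when the pool mean was removed. A leave-out leaves 1 promoter with a lone pool, which limma takes to vary like the others. With promoters 1 to 4 alone, only 3 of the 8 windows of promoter 3 were tested.

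With the replicate number as a replicate block, the share of variance of the SD was 0.872 with an exact permutation p of 0.0833, high windows numbered 24, low windows 31 and windows of promoter 3 numbered 3, and no other call changed. Same-numbered pools did not deviate together: over 9 pairs of promoters the correlation of the replicate difference across windows ran from -0.111 to 0.231 (median 0.0608), so the number does not pair the pools. Alternatives on DNA read minimums, pseudocounts, reporters without RNA and normalization from reads were not run, since the table used holds no reads, nor were those on gene windows. Low read numbers per barcode limit single reporters to an unknown degree.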

Other observations

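The comparisons of tracks were chosen after the values were seen; the tests of neighbours and of strand pairs were set before. Of 6 tracks of HP1 heterochromatin 5 were positive and 1 was negative, beside 78 positive of all 112 tracks. HP1 had a mean rho of 0.0997 ± 0.0263, H3K9ME2 0.148 ± 0.043, SU.VAR.3.7 0.0962 ± 0.0382, HP3 0.0660 ± 0.0253 and HP6 0.0610 ± 0.0266, positive in 10 of 10 pools each, while SU.VAR.3.9, the histone methyltransferase of this chromatin, was negative at -0.0558 ± 0.0401 in 10 of 10 pools (adjusted exact permutation p = 0.00277 each). Without chromosome 4 and the proximal 2 Mb the values were 0.0860 for HP1, 0.141 for H3K9ME2 and -0.0715 for SU.VAR.3.9. On chromosome 4 the median site lay at percentile 95.9 for HP1, 88.0 for SU.VAR.3.7 and 79.8 for SU.VAR.3.9, but at 51.8 for LAM and 49.5 for SUUR. The nucleoporin tracks went in opposite directions, with 0.0469 ± 0.0385 for NUP50 (9 of 10 pools positive, adjusted exact permutation p = 0.00962) and -0.0313 ± 0.0323 for NUP98 (7 of 10 pools negative, adjusted exact permutation p = 0.0179).

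A hypothesis was that expression of nearby reporters carries information that the 112 tracks do not. For each pool, expression on an arm was predicted from the tracks at the site and their mean over insertions within 10 kb, with a model from the other arms. The prediction had a mean Spearman rho of 0.450 ± 0.181 (SD, n = 10 pools), close to the 0.428 ± 0.191 of the mean of at least 3 reporters of other promoters, promoter 0 left out as a source, within 10 kb (difference -0.022 ± 0.040, exact permutation p = 0.117). What the tracks left over still correlated with the neighbours at 0.137 ± 0.109 (8 of 10 pools positive, exact permutation p = 0.00781). That missed the 9 pools set beforehand, because both pools of promoter 0 were near 0 (-0.0092 and -0.0090), so the hypothesis stays open. With promoter 3 the values were 0.297 and 0.301. Tracks at the resolution used may also miss part of the chromatin signal that neighbours reflect.

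The strand difference of the report was tested in pairs of neighbours on opposite strands under 1 kb apart, of which there were 6754. The plus strand minus the minus strand was -0.038 ± 0.239 (6 of 10 pools negative, exact permutation p = 0.605), which neither excludes a small difference nor shows one.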
